A study of Mus musculus with 12 samples.

How the data were processed

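Total RNA from abdominal fat pads of female C57BL/6 mice, either wild type or null for p47phox, was measured on 12 Affymetrix arrays of 45101 probe sets each. Each array held a pool of fat pads, with 3 pools in each of 4 groups: wild type on casein, null on casein, wild type on the high fat diet and null on the high fat diet. Per the labels, the diets began at postnatal day 28 and lasted 13 weeks, and biotin-labelled RNA was made from 8 µg of total RNA. The number of animals in a pool is not given, so every p-value of a single gene here measures the spread between pools. No array carries a date or batch. For arrays, their number limits the precision.

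Per the submitters' processing notes, GCOS and RMA were used, with no version, order or setting stated. The deposited values are log2 values of the kind RMA gives, per the labels that name RMA. The base of the logarithm is not stated and was taken as 2, because RMA gives log2 values. In the deposited file the median of every probe set over the 12 arrays is 0 (0 of 45101 probe sets depart from it by more than 1e-06), so the authors had centred each probe set. Expression levels and signal over background are therefore lost, and only differences between arrays can be read. The span of a probe set over the 12 arrays had a median of 0.56 and reached 10.32 on the log2 scale.

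The platform's annotation gives 1 gene for 34958 probe sets, several genes for 932 and no gene for 9211; the last 2 kinds were left out. Current symbols came from the RefSeq table of the assembly GRCm38.p6, which held 34754 of the 34958 probe sets by their gene identifier and served only for names and for which genes are neighbours. The remaining probe sets stand for 18195 genes, of which 9011 have more than 1 probe set. The value of a gene is the mean of its probe sets.

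Before the data were examined, the plan was to keep probe sets at or above the median of all values in at least 3 arrays and to let the probe set with the highest mean stand for its gene. On centred values that filter removes 0 of the 45101 probe sets, and the highest mean no longer picks the brightest probe set. Once the values were seen to be centred, the mean of a gene's probe sets, which the plan held as an alternative, was taken in its place, and the rule of the plan was run as an alternative. The comparisons, the threshold, the 28 gene lists, the rule for the genes named and the other alternatives not described as added were chosen with that plan.

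Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) in 1 fit of the 4 group means to all 12 arrays, with 8 residual degrees of freedom and an estimated 2.5 prior degrees of freedom. The p-values were two-sided and adjusted over the 18195 genes by the method of Benjamini and Hochberg, with a threshold of 0.05. The 5 comparisons were high fat diet minus casein in wild type pools and in null pools, null minus wild type on casein and on the high fat diet, and the interaction, which is the diet change in null pools minus that in wild type pools. A pair of comparisons averaged over the other factor was added after seeing the data. Errors printed after ± are standard errors (SE) of the fit or, where said, standard deviations (SD), with n = 3 pools in each group. A gene is called separated when all 3 pools of one group lie above or below all 3 of the other.

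The 28 gene lists cover adipocytes, lipid and energy metabolism, immune cells, matrix, vessels, other tissues that a fat pad can hold, stress, the clock, the cell cycle and the surroundings of the Ncf1 gene. Each list was tested with camera of limma, with a preset correlation of 0.01 between genes and adjustment over the 28 lists, and again with a correlation estimated from the residuals. With the preset, camera compares a list with other genes, so its p-value does not measure the spread of the list between pools. The fry test of limma was run beside it; it asks whether the members of a list move one way on balance and does not compare them with other genes. For each list the members past the threshold were counted over all genes and adjusted over the list alone. A further 5 lists, for ovary cells, oviduct and uterine epithelium, liver, adrenal gland and kidney, were written after the data were seen and were not tested with camera. They gave medians in each pool. The liver medians also served as a covariate, and those of ovary cells and of oviduct and uterine epithelium in tests of explanations.

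The genes named are the 8 with the largest rise and the 8 with the largest fall among separated genes past the threshold in each of the 4 simple comparisons, and the 5 largest each way for the interaction; where fewer than 4 passed, the 4 with the smallest p. Up to 4 members are named in each list that camera called and in the NADPH oxidase list, those past the threshold first. A further 10 genes were followed in every comparison: Ncf1, Cybb, Lep, Adipoq, Fasn, Ucp1, Ccl2, Adgre1, Mest and Nnt. Predicted genes and clones were counted but not named. The planned share of genes changed on one diet or genotype that moved the same way on the other has no value, because 0 genes passed in the comparisons it starts from, so correlations over all genes are given.

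Alternatives chosen with the plan were no filter and a stricter filter, the variance model with trend and robust settings, array weights, quantile normalization of the deposited values again, centring of each array on its median, pool numbers as a replicate block, each probe set tested on its own, only the groups of the comparison in the fit, a looser threshold, and leaving out each of the 12 pools in turn. Alternatives added after seeing the data were the probe set with the highest mean or the largest SD, only the genes with the larger SD, array medians of the reproductive tract, skeletal muscle and liver lists as 3 covariates, and a fit without 3 pools that stand apart in markers of other tissues: wild type casein pool 3, wild type high fat diet pool 2 and null high fat diet pool 1. Wild type casein pool 1 was kept in that fit, with medians of 2.77 for skeletal muscle markers and 2.5 for oviduct and uterine epithelium genes.

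The tests were tested on simulated data with the spread and the array number of this study, in which 200 of 18195 genes were changed. limma called from 67.2% to 88.1% of the genes changed 2-fold, from 94.0% to 97.0% of those changed 4-fold and from 95.5% to 100% of those changed 8-fold, with 8 to 13 calls among unchanged genes and 0 calls when no gene was changed. camera called the list of mature adipocyte markers when it was shifted by 0.5 in each of the 5 comparisons, with 0 other lists called. The simulated genes varied independently of each other. The simulation therefore does not show how often genes or lists are falsely called when genes are correlated, as in real pools. The changed genes were drawn at random from all genes, so the shares called do not describe genes with a large spread between pools.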

Results

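Gene expression was measured in abdominal fat pads of female C57BL/6 mice that were wild type or lacked p47phox, the cytosolic subunit encoded by Ncf1 that activates the superoxide-making NADPH oxidase of phagocytes. Mice of each genotype were fed casein or a high fat diet for 13 weeks from postnatal day 28. The 12 arrays hold 3 pools of fat pads in each of the 4 groups and report 18195 genes. Values are on the log2 scale and centred on the median of the 12 arrays, so they show differences between pools and not expression levels. The number of arrays limits the precision.

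Markers of other tissues varied among the pools of a group. The median of 22 skeletal muscle markers was 4.57 in wild type high fat diet pool 2, 3.67 in null high fat diet pool 1 and 2.77 in wild type casein pool 1, against -1.79 in wild type high fat diet pool 1. In wild type casein pool 3 the medians were 4.61 for 18 liver genes, 3.71 for 10 adrenal gland genes and 1.42 for 29 lymphocyte markers. The median of 23 ovary, oviduct and uterus markers lay from -0.73 to 0.04 in wild type casein pools, from -0.09 to 0.35 in null casein pools, from -0.56 to -0.47 in wild type high fat diet pools and from 0.13 to 0.78 in null high fat diet pools. The median of 19 pancreas markers stayed between -0.08 and 0.07 in the 12 pools.

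**Figure D1:**
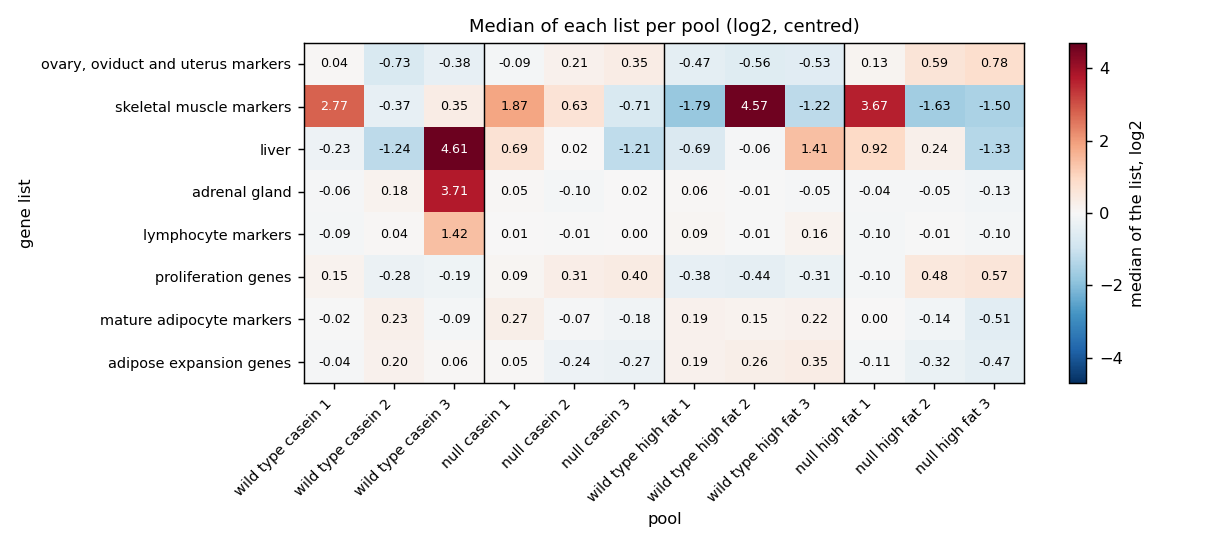
Median log2 value of 8 gene lists (vertical axis) in each of the 12 pools (horizontal axis), centred on the median of the 12 arrays; colour and number give the median. Wild type casein pool 3 stands out for liver genes at 4.61, and the ovary, oviduct and uterus markers run from -0.56 to -0.47 in wild type and from 0.13 to 0.78 in null pools on the high fat diet.

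The level of Ncf1 was read first, since the null genotype disrupts this gene. Ncf1 was lower in all 6 null pools than in all 6 wild type pools for 2 of its 3 probe sets. The probe set with the widest gap ran from 0.33 to 1.71 in wild type pools and from -0.54 to -0.33 in null pools. The next ran from 0.16 to 0.83 and from -0.27 to -0.16, and the last overlapped, at -0.27 to 0.26 and -0.15 to 0.03. The mean of the 3 probe sets of Ncf1 fell by 0.76 ± 0.16 (SE, n = 3 pools a group; limma adjusted p = 0.0312) in null pools on the high fat diet, and its difference on casein was -0.65 ± 0.16 (adjusted p = 0.521). The call for Ncf1 on the high fat diet ended without null casein pool 2 (adjusted p = 0.051), wild type high fat diet pool 1, 2 or 3 (adjusted p = 0.0575, 0.0712 and 0.102), or null high fat diet pool 2 or 3 (adjusted p = 0.1 and 0.109). Over its alternatives the adjusted p of Ncf1 ran from 0.00122 to 0.709.

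**Figure D2:**
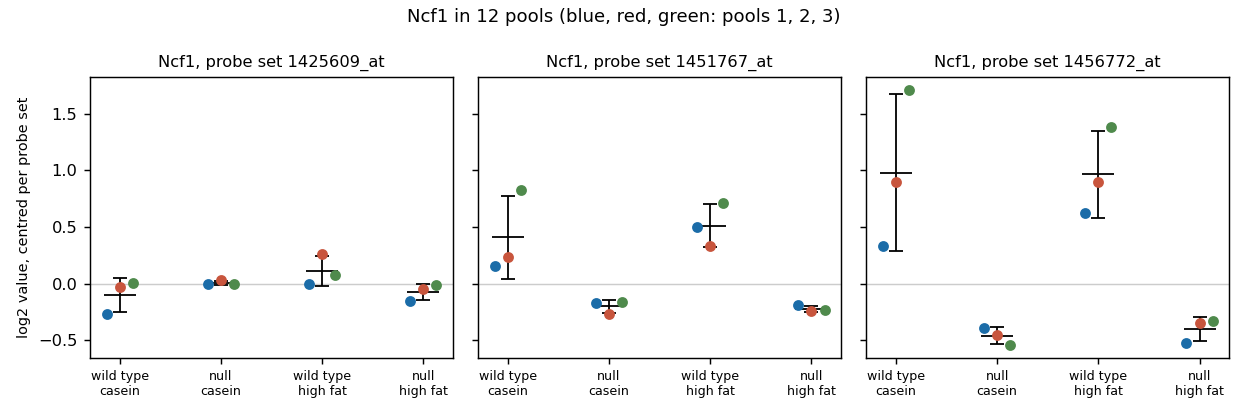
Centred log2 value (vertical axis) of each of the 3 probe sets of Ncf1 in the 4 groups (horizontal axis); points are pools, bars are mean ± SD of 3 pools. For the probe set with the widest gap the null pools lie between -0.54 and -0.33 and the wild type pools between 0.33 and 1.71.

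The genotypes were compared on the high fat diet to ask how the loss of p47phox alters fat under that diet. Mest, Lep and Npr3 fell in the null pools, while Adipoq and Fasn did not pass. Mest, an imprinted gene whose expression follows fat mass expansion, fell by 2.76 ± 0.46 (SE, n = 3 pools a group; adjusted p = 0.021), from 1.79 ± 0.96 (SD) in wild type pools to -0.97 ± 0.32 (SD) in null pools. Lep, which encodes the satiety hormone leptin, fell by 1.64 ± 0.28 (adjusted p = 0.0225), and Npr3, the clearance receptor for natriuretic peptides, fell by 2.39 ± 0.36 (adjusted p = 0.0165). Aqp7, the glycerol channel of adipocytes, fell by 1.17, and the adipocyte transcription factors Pparg and Cebpa fell by 0.78 and 0.53. The difference in Adipoq, which encodes adiponectin, was -0.20 ± 0.18 (adjusted p = 0.536), and that in Fasn, fatty acid synthase, was 0.05 ± 0.22 (adjusted p = 0.913). The calls of Mest, Lep and Npr3 ended without wild type high fat diet pool 3 (adjusted p = 0.0589, 0.0504 and 0.0657), without null high fat diet pool 2 (adjusted p = 0.0737, 0.087 and 0.0737) and without null high fat diet pool 3 (adjusted p = 0.0801, 0.0834 and 0.0738). With the medians of the reproductive tract, skeletal muscle and liver lists as covariates, Cebpa turned to 0.025. Adipoq stood at -0.36 without null high fat diet pool 1 and at 0.02 without null high fat diet pool 3.

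Among 23 mature adipocyte markers 5 fell over all genes and 11 adjusted over the list alone, with a median of -0.51. Camera called the list lower (adjusted p = 1.12e-05; adjusted p = 0.487 with an estimated correlation). Of 17 adipose expansion genes, which respond to growth of fat mass, 5 fell over all genes and 8 adjusted over the list alone, with a median of -0.52 (camera adjusted p = 8.73e-06; adjusted p = 0.402 with an estimated correlation). They include Mest, Npr3, Lep and Cav2, a caveolin, which fell by 0.77 ± 0.18 (adjusted p = 0.0362). Among 21 endothelial markers 3 fell over all genes and 14 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 1.81e-06; adjusted p = 0.402 with an estimated correlation). Those 3 were Rgcc, Pecam1, the platelet and endothelial cell adhesion molecule, and Esam, which fell by 0.68, 0.62 and 0.49. The ovary, oviduct and uterus markers, at a median of -0.56 to -0.47 in the wild type and 0.13 to 0.78 in the null pools, separated the same pools as these 3 lists. With the medians of the reproductive tract, skeletal muscle and liver lists as covariates 0 of these 3 lists were called. The mature adipocyte median then turned to 0.09 and the endothelial median to 0.04, and that of the adipose expansion genes was -0.13.

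Among the largest rises in the null pools were those of Hsd3b1 and Inha. Hsd3b1, which makes progesterone in steroid-producing cells, rose by 8.26 ± 1.86 (SE, n = 3 pools a group; adjusted p = 0.0345), and Inha, the inhibin subunit of ovarian granulosa cells, rose by 6.79 ± 1.32 (adjusted p = 0.0261). Of 23 ovary, oviduct and uterus markers 6 rose over all genes and 14 adjusted over the list alone, with a median of 1.11 (camera adjusted p = 7.52e-10; adjusted p = 0.402 with an estimated correlation). They include Cyp11a1, the first enzyme of steroid synthesis, which rose by 2.56, and Zp3, an oocyte coat protein, which rose by 2.23. The other genes among the 8 largest rises, Mgarp, Hao2, Akr1cl, Prss35, Acsbg1 and Kctd14, rose by 4.32 to 6.01. Hsd3b1 was at -0.18, -8.11 and 1.14 in wild type casein pools 1, 2 and 3, and at -0.05 to 0.78 in the null pools of both diets. In that pool 3 the adrenal gland median was 3.71 and Inha was at -5.04, so Hsd3b1 alone does not mark ovary there. The call of Hsd3b1 ended without null casein pool 2 (adjusted p = 0.0563) or wild type high fat diet pool 1, 2 or 3 (adjusted p = 0.0661, 0.092 and 0.103). It also ended without null high fat diet pool 2 or 3 (adjusted p = 0.109 and 0.125). The call of Inha ended without wild type high fat diet pool 1, 2 or 3 (adjusted p = 0.0652, 0.0587 and 0.0838) and null high fat diet pool 2 or 3 (adjusted p = 0.0948 and 0.098).

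Cell cycle genes were higher in null pools on the high fat diet. Of 28 proliferation genes 8 rose over all genes and 21 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 5.88e-12; adjusted p = 0.402 with an estimated correlation). Ccnb2, a mitotic cyclin, rose by 1.91 ± 0.49 (adjusted p = 0.0489), Cdk1, its kinase, by 1.65, Cdc20 by 1.19 and Rrm2, a ribonucleotide reductase subunit, by 1.11. Of 29 interferon-stimulated genes 2 rose over all genes, and adjusted over the list alone 7 rose and 1 fell, with a median of 0.30 (camera adjusted p = 0.000383; adjusted p = 0.402 with an estimated correlation). Usp18 rose by 0.94 and Igtp, an interferon-induced GTPase, by 0.49. Of 15 mesothelial markers 2 rose over all genes and 4 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 0.000455; adjusted p = 0.487 with an estimated correlation). Wt1 rose by 2.61 and Clu by 1.93. Of 28 mammary and other epithelial markers 1 rose over all genes, Wfdc18 by 3.56 ± 0.91 (adjusted p = 0.0477), and 10 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.00341; adjusted p = 0.508 with an estimated correlation). Medians of the ovary, oviduct and uterus markers of 0.13, 0.59 and 0.78 in the 3 null pools stood beside medians of -0.10, 0.48 and 0.57 for the proliferation genes. With the tissue list medians as covariates the proliferation list turned to -0.08 and was not called, and Ccnb2, Cdk1 and Rrm2 turned to -0.38, -0.02 and -0.09. The mammary and other epithelial list turned to -0.25 and camera called it lower, while Wfdc18 and Clu turned to -0.25 and -0.27. The medians were 0.12 for interferon-stimulated genes and 0.68 for mesothelial markers, neither called. The interferon median was 0.19 without null high fat diet pool 3. The mesothelial median was 1.04 without wild type high fat diet pool 1, and 0.17 without wild type high fat diet pool 3, where its call ended.

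Macrophage markers were lower in null pools on the high fat diet as a list: 0 of 39 passed over all genes and 0 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.00204; adjusted p = 0.681 with an estimated correlation). Mrc1, the mannose receptor, differed by -0.94 ± 0.28 (adjusted p = 0.0728), Adgre1, which encodes F4/80, by -0.46 ± 0.18 (adjusted p = 0.148) and the chemokine Ccl2 by -0.70 ± 0.30 (adjusted p = 0.182). Of 20 adipocyte progenitor and fibroblast markers 1 fell over all genes and 1 adjusted over the list alone, Ebf1 by 0.72, with a median of -0.19 (camera adjusted p = 0.0205; adjusted p = 0.508 with an estimated correlation). Of 8 erythroid genes 1 fell over all genes, Slc4a1, the band 3 anion exchanger, by 0.81, and 3 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0231; adjusted p = 0.487 with an estimated correlation). Of 42 genes in the oxidative phosphorylation list, which also holds citric acid cycle enzymes, 1 fell over all genes, the citric acid cycle enzyme Idh3a by 0.68, and 0 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0134; adjusted p = 0.819 with an estimated correlation). Of 23 fatty acid oxidation genes 0 passed by either count, with a median of -0.20 (camera adjusted p = 0.0345; adjusted p = 0.819 with an estimated correlation). List calls ended without wild type high fat diet pool 2 for oxidative phosphorylation (median -0.07), fatty acid oxidation (-0.12), progenitor and fibroblast markers (-0.16) and erythroid genes (-0.16). They ended without wild type high fat diet pool 3 for macrophage markers (-0.13). They also ended without wild type high fat diet pool 1 for oxidative phosphorylation (-0.13), without null high fat diet pool 3 for fatty acid oxidation (-0.14) and without null high fat diet pool 1 for erythroid genes (-0.20). The macrophage median was -0.42 without wild type high fat diet pool 1, and that of oxidative phosphorylation was -0.25 without pool 3. Without that pool 3 Adgre1 stood at -0.26 and Ccl2 at -0.30. With the tissue list medians as covariates fatty acid oxidation turned to 0.41, and camera called it higher. Oxidative phosphorylation turned to 0.16 and the progenitor and fibroblast list to 0.06, neither called. Macrophage markers were at -0.09, not called, and erythroid genes at -0.37, still called lower. In the NADPH oxidase list Ncf1 fell, 1 of 13 genes by either count (camera adjusted p = 0.147). Cybb, the catalytic subunit in phagocytes, differed by -0.50 ± 0.18 (adjusted p = 0.124), Duox1 by -0.47 and Cyba by 0.28. Leaving out 1 pool moved Cyba to 0.14 and 0.495 without wild type high fat diet pools 1 and 3, and to 0.43 and 0.18 without null high fat diet pools 1 and 3. The 15 lists that camera did not call, among them lipogenesis, cholesterol synthesis, brown and beige adipocyte genes and skeletal muscle markers, had adjusted p from 0.0898 to 0.998. The neighbours of Ncf1 on chromosome 5 stood at a median of -0.03 (camera adjusted p = 0.998), antioxidant genes at -0.01 (camera adjusted p = 0.744) and circadian clock genes at -0.13 (camera adjusted p = 0.871). The largest falls of single genes included Rnase2a, an eosinophil-type ribonuclease, by 2.71, Prr32 by 2.14, Folh1, a glutamate carboxypeptidase, by 1.94, Pcolce2 by 1.91, Tfpi2 by 1.76 and Pla2g2e, a secreted phospholipase, by 1.65.

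In all, 1077 of 18195 genes passed in limma between the genotypes on the high fat diet, 584 higher and 493 lower in null pools. Of these 251 differed by more than 2-fold, 204 higher and 47 lower. Groups were separated for 5866 genes, 32.2% where chance gives 10%, and 1076 of these were among the 1077. The fry test called 7 of the 28 lists. The count was 0 without null high fat diet pool 2 or without null high fat diet pool 3, so that every single-gene call on this diet, Mest, Lep and Ncf1 included, ended there. It was 32, 170 and 210 without wild type high fat diet pool 3, 1 and 2, 456 without null casein pool 2 and 1617 without null high fat diet pool 1. Of the 38 named genes that passed, 2, 10 and 8 passed without wild type high fat diet pool 3, 1 and 2, 17, 27 and 31 without null casein pool 2, 3 and 1. The number was 33 and 36 without wild type casein pool 3 and 2, and 35 without null high fat diet pool 1. The count over all genes was 0 with the medians of the reproductive tract, skeletal muscle and liver lists as covariates, 440 without the 3 pools that stand apart in other tissue markers, 655 after quantile normalization again and 5116 with array weights. With the probe set of the highest mean, the rule of the plan, the count was 732. Of these 616 were among the 1077, and 22 of the 38 named genes passed while 16 did not. The reproductive tract median separated the genotypes on this diet, so the fit with covariates, with 5 residual degrees of freedom, can hardly tell that tissue from the genotype. With the 3 pools left out it still separated them, at -0.47 and -0.53 in wild type and 0.59 and 0.78 in null high fat diet pools.

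**Figure D3:**
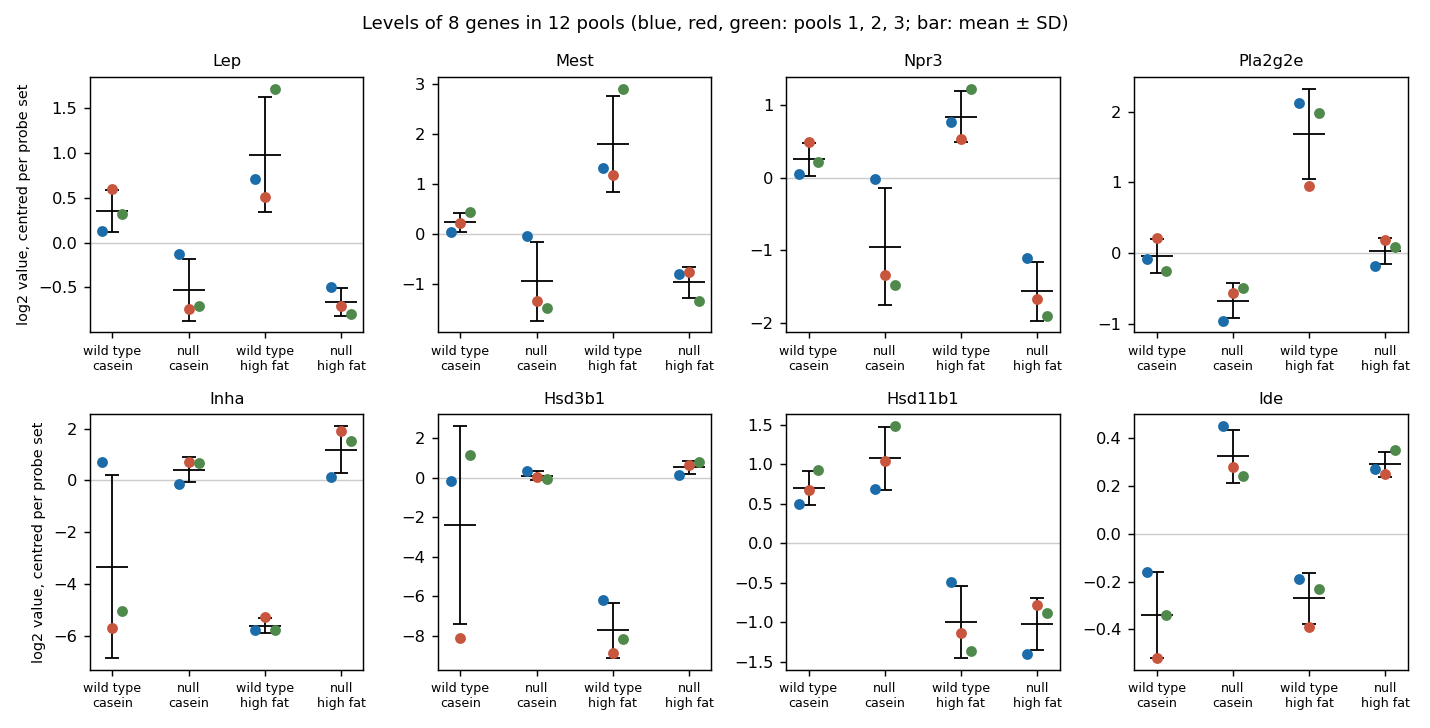
Centred log2 value (vertical axis) of 8 genes in the 4 groups (horizontal axis); points are pools, bars are mean ± SD of 3 pools. Mest, Lep and Npr3 are lower in all 3 null than in all 3 wild type pools on the high fat diet, and Inha is at 0.73 in wild type casein pool 1 against -5.68 and -5.04 in the other 2 pools of that group.

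The genotypes were also compared on casein, to ask what the loss of p47phox changes without the high fat diet. Nol3, an inhibitor of cell death, differed by -0.93 ± 0.14 (SE, n = 3 pools a group), and Ide, the insulin-degrading enzyme, by 0.66 ± 0.10. With Irak1bp1 at 0.53 and Hirip3 at 0.46 these had the smallest adjusted p of 0.184 and did not pass. The pools of all 4 genes were separated, which their choice by the smallest p favours. Lep differed by -0.88 ± 0.28 (adjusted p = 0.549), Mest by -1.17 ± 0.46 (adjusted p = 0.583) and Npr3 by -1.20 ± 0.36 (adjusted p = 0.542), with all 3 null pools below all 3 wild type pools. Ucp1, the uncoupling protein of brown and beige adipocytes, differed by -3.69 ± 1.51 (adjusted p = 0.592), and by -1.68 without null casein pool 1. The difference was 0.04 ± 0.18 for Adipoq (adjusted p = 0.963), -0.07 for Fasn, 0.11 for Ccl2, 0.17 for Adgre1 and 0.11 for Nnt.

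As lists, on casein, proliferation genes were higher in null pools with a median of 0.37 (camera adjusted p = 3.78e-11; adjusted p = 0.551 with an estimated correlation) and interferon-stimulated genes with 0.23 (camera adjusted p = 1.26e-08; adjusted p = 0.403 with an estimated correlation). Higher lists were also the ovary, oviduct and uterus markers at 0.49 and the unfolded protein response genes at 0.13 (both adjusted p = 0.551 with an estimated correlation). So were, at adjusted p = 0.594 with an estimated correlation, the mammary and other epithelial markers at 0.24, the mesothelial markers at 0.28 and the matrix and fibrosis genes at 0.09. Lower lists were oxidative phosphorylation at -0.18, fatty acid oxidation at -0.26, lymphocyte markers at -0.45 and brown and beige adipocyte genes at -0.40 (all adjusted p = 0.594 with an estimated correlation), and adipose expansion genes at -0.21 (adjusted p = 0.553 with an estimated correlation). In these 12 lists 0 members passed over all genes. Adjusted over the list alone, 2 interferon-stimulated genes were higher and 1 lymphocyte marker was lower. Examples, none past the threshold, are Ccnb2 at 1.28 ± 0.49, Birc5 at 1.26 ± 0.48, Iigp1 at 0.70 ± 0.15, Timp1 at 2.10 ± 0.60, Creld2 at 0.56 ± 0.21 and Suclg1, a citric acid cycle enzyme, at -0.57 ± 0.21. Ccnb2 stood at 0.81, Creld2 at 0.37 and Suclg1 at -0.37 without wild type casein pool 2. Without wild type casein pool 3, where the lymphocyte median was 1.42 and the liver median 4.61, the lymphocyte list stood at 0.02 and the matrix list at -0.003. Without wild type casein pool 1 the medians were -0.52 for fatty acid oxidation, -0.28 for oxidative phosphorylation, -0.62 for brown and beige adipocyte genes and -0.735 for lymphocyte markers. They were 0.50 for mammary and other epithelial markers and 0.18 for mesothelial markers. Oxidative phosphorylation was at -0.08 and the matrix genes at 0.14 without wild type casein pool 2. Without null casein pool 1 adipose expansion genes were at -0.34 and mammary and other epithelial markers at 0.53. With the tissue list medians as covariates fatty acid oxidation turned to 0.06 and the ovary, oviduct and uterus markers to -0.03, neither called. The mammary and other epithelial markers turned to -0.01, and camera called them lower.

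Across the genotypes on casein 0 of 18195 genes passed in limma, with 1478 at an unadjusted p under 0.05, and 2178 were separated, 12% where chance gives 10%. The count was 46 without wild type casein pool 1, whose ovary, oviduct and uterus median was the highest of the 6 wild type pools at 0.04, 2 without wild type casein pool 2, and 1 after quantile normalization again. The fry test called 0 of the 28 lists, and camera called 5 in place of 12 without wild type casein pool 2 and 7 without wild type casein pool 3. Without pool 2 the medians of lists no longer called were -0.15 for adipose expansion genes, -0.12 for fatty acid oxidation, -0.21 for brown and beige adipocyte genes, and 0.06 for mammary and other epithelial markers. They were 0.40 for ovary, oviduct and uterus markers, 0.18 for mesothelial markers and 0.16 for the unfolded protein response. Without wild type casein pool 3 they were 0.21 for mammary and other epithelial markers, 0.17 for mesothelial markers and 0.12 for the unfolded protein response. Calls also ended without null casein pool 1 for brown and beige adipocyte genes (-0.23), mesothelial markers (0.18), matrix genes (0.02) and the unfolded protein response (0.07). They ended without null casein pool 2 for matrix genes (0.12) and mesothelial markers (0.31). They ended without null casein pool 3 for adipose expansion genes (-0.17) and mammary and other epithelial markers (0.05). Without wild type high fat diet pool 3 the call ended for the unfolded protein response (0.13), and without wild type high fat diet pool 2 or null high fat diet pool 1 or 3 for matrix genes (0.09).

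The diets were compared in wild type pools to ask how the high fat diet alters fat in mice with an intact oxidase. Hsd11b1, which regenerates active glucocorticoid, differed by -1.69 ± 0.26 (SE, n = 3 pools a group; adjusted p = 0.208), and the secreted phospholipase Pla2g2e by 1.73 ± 0.27 (adjusted p = 0.208). The smallest adjusted p was that of Slc16a12, a monocarboxylate transporter family member, at 1.14 ± 0.13 (adjusted p = 0.0746), and Gprin2 stood at -0.83 ± 0.13 (adjusted p = 0.208). None passed. All 4 were separated, which their choice by the smallest p favours. Mest differed by 1.56 ± 0.46 (adjusted p = 0.538), Lep by 0.63 ± 0.28 (adjusted p = 0.654), Ccl2 by 0.70 ± 0.30 (adjusted p = 0.652), Adgre1 by 0.46 ± 0.18 (adjusted p = 0.639) and Ucp1 by -3.13 ± 1.51 (adjusted p = 0.67). The difference was 0.08 ± 0.18 for Adipoq, -0.33 ± 0.22 for Fasn, 0.25 ± 0.18 for Cybb and 0.03 ± 0.19 for Nnt. Without wild type high fat diet pool 3 the differences were 1.01 for Mest, 0.26 for Lep, 0.30 for Ccl2, 0.26 for Adgre1, -0.07 for Fasn and 0.105 for Cybb. Fasn was at -0.51 without wild type high fat diet pool 1, and Cybb at 0.07 and 0.45 without wild type casein pools 1 and 3.

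Of the lists that camera called in wild type pools, higher on the high fat diet were endothelial markers with a median of 0.34 (camera adjusted p = 2.35e-08), macrophage markers with 0.31 (camera adjusted p = 2.78e-07) and matrix and fibrosis genes with 0.24 (each adjusted p = 0.468 with an estimated correlation). Higher too were adipose expansion genes with 0.30, adipocyte progenitor and fibroblast markers with 0.21 and inflammatory genes with 0.10 (each adjusted p = 0.468 with an estimated correlation), and mature adipocyte markers with 0.10 (adjusted p = 0.627 with an estimated correlation). Lower were brown and beige adipocyte genes at -0.53 (camera adjusted p = 3.41e-06) and ovary, oviduct and uterus markers at -0.41, both at adjusted p = 0.468 with an estimated correlation. Oxidative phosphorylation at -0.14, fatty acid oxidation at -0.16, lymphocyte markers at -0.32, proliferation genes at -0.22 and mammary and other epithelial markers at -0.18 were lower too, all at adjusted p = 0.627 with an estimated correlation. No member of these 14 lists passed over all genes or adjusted over the list alone. Examples, none past the threshold, are the macrophage proteases Mmp12 at 1.43 ± 0.63 and Ctsk at 0.82 ± 0.31, the eosinophil chemokine Ccl11 at 1.05 ± 0.35, the matrix protease Mmp3 at 1.64 ± 0.43, Ramp2 at 0.44 ± 0.15, and the brown fat genes Elovl3 at -2.41 ± 0.72 and Cidea at -2.53 ± 1.01. The macrophage median was 0.63 in wild type high fat diet pool 3 and 0.20 and -0.02 in pools 2 and 1. Without that pool 3 Mmp12 stood at 0.57 and Ctsk at 0.535, and without pool 1 Mmp12 stood at 2.325. The lymphocyte median turned to 0.10 without wild type casein pool 3, whose lymphocyte median was 1.42.

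Between the diets in wild type pools 0 of 18195 genes passed in limma, with 1384 at an unadjusted p under 0.05, and 2172 were separated, 11.9% where chance gives 10%. The count was 15 without wild type casein pool 2, 2 without wild type high fat diet pool 1, 1 without wild type high fat diet pool 2 and 1 without the 3 pools that stand apart. The fry test called 0 of the 28 lists. List calls ended without wild type casein pool 1 for ovary, oviduct and uterus markers (median -0.09), proliferation genes (-0.04), mammary and other epithelial markers (-0.07), mature adipocyte markers (0.12) and inflammatory genes (0.09). They ended without wild type casein pool 2 for fatty acid oxidation (-0.002), oxidative phosphorylation (-0.04) and inflammatory genes (0.13). They ended without wild type high fat diet pool 3 for oxidative phosphorylation (-0.05) and inflammatory genes (0.01). Without that last pool the macrophage median was 0.13, the matrix median 0.09 and the adipose expansion median 0.17. Without wild type casein pool 2 the medians were 0.29 for mature adipocyte markers, -0.72 for ovary, oviduct and uterus markers and -0.53 for lymphocyte markers. Without wild type casein pool 1 they were -0.33 for fatty acid oxidation, -0.22 for oxidative phosphorylation and -0.57 for lymphocyte markers. The matrix median was 0.115 without wild type casein pool 3. Without wild type high fat diet pool 2 oxidative phosphorylation was at -0.23 and the mammary and other epithelial markers at -0.12.

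The same diets in null pools ask for the response without p47phox. Hsd11b1 differed by -2.09 ± 0.26 (SE, n = 3 pools a group; adjusted p = 0.163), the smallest adjusted p, with all 3 high fat diet pools below all 3 casein pools. The potassium channel gene Kcnj15 stood at -0.94 ± 0.17, Acsl3, which activates long-chain fatty acids, at 0.77 ± 0.14 and Cpxm1 at 0.65 ± 0.12, each with an adjusted p = 1. Lep differed by -0.13 ± 0.28, Mest by -0.02 ± 0.46, Adipoq by -0.16 ± 0.18, Fasn by -0.20 ± 0.22, Ucp1 by -0.85 ± 1.51, Ccl2 by -0.12 ± 0.30, Adgre1 by -0.17 ± 0.18, Cybb by -0.02 ± 0.18 and Nnt by 0.05 ± 0.19. Ucp1 was at -4.89, 1.41 and 0.86 in null casein pools 1, 2 and 3, and at -2.53, -1.05 and -1.6 in the null high fat diet pools.

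In null pools camera called oxidative phosphorylation lower on the high fat diet with a median of -0.12 (camera adjusted p = 3.5e-05), with mature adipocyte markers at -0.18, fatty acid oxidation at -0.11 and endothelial markers at -0.08, and called mesothelial markers higher at 0.32 and cholesterol synthesis genes at 0.08, all at adjusted p = 0.929 with an estimated correlation. Erythroid genes were lower at -0.24 (camera adjusted p = 6.06e-05; adjusted p = 0.505 with an estimated correlation). No member of these 7 lists passed over all genes or adjusted over the list alone. Examples, none past the threshold, are Slc4a1 at -0.60 ± 0.19, Aqp7 at -0.70 ± 0.27, Ndufb3, a subunit of complex I, at -0.25 ± 0.10, Rgcc at -0.41 ± 0.17, Wt1 at 0.81 ± 0.56 and Insig1 at 0.52 ± 0.27. Without null casein pool 1 Aqp7 was at -0.45, Rgcc at -0.185 and Insig1 at 0.20. The ovary, oviduct and uterus markers were at a median difference of 0.18 (camera adjusted p = 0.0535). Between the diets in null pools 0 of 18195 genes passed in limma, with 727 at an unadjusted p under 0.05, and 1927 were separated, 10.6% where chance gives 10%. The count was 942 with array weights, 1 with the trend and robust settings and 1 without wild type casein pool 3. The fry test called 0 of the 28 lists, and camera called 2 in place of 7 without null high fat diet pool 3. Without that pool the lists no longer called were mature adipocyte markers (median -0.08), cholesterol synthesis (0.03), fatty acid oxidation (-0.06), endothelial markers (-0.005) and mesothelial markers (0.23). Calls also ended without null casein pool 1 for mature adipocyte markers (-0.09), cholesterol synthesis (0.02) and endothelial markers (-0.04). They ended without null casein pool 2 for fatty acid oxidation (-0.10) and endothelial markers (-0.07), and without null casein pool 3 or null high fat diet pool 1 for mesothelial markers (0.26 and 0.28). Without null high fat diet pool 1 the medians were -0.335 for mature adipocyte markers, -0.18 for fatty acid oxidation, -0.16 for endothelial markers and 0.15 for cholesterol synthesis. Cholesterol synthesis was at 0.13 without null high fat diet pool 2 or null casein pool 3 and at 0.125 without null casein pool 2. The endothelial median was -0.15 without null casein pool 3. With the tissue list medians as covariates mature adipocyte markers turned to 0.02, fatty acid oxidation to 0.05 and endothelial markers to 0.06, none called.

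**Figure D4:**
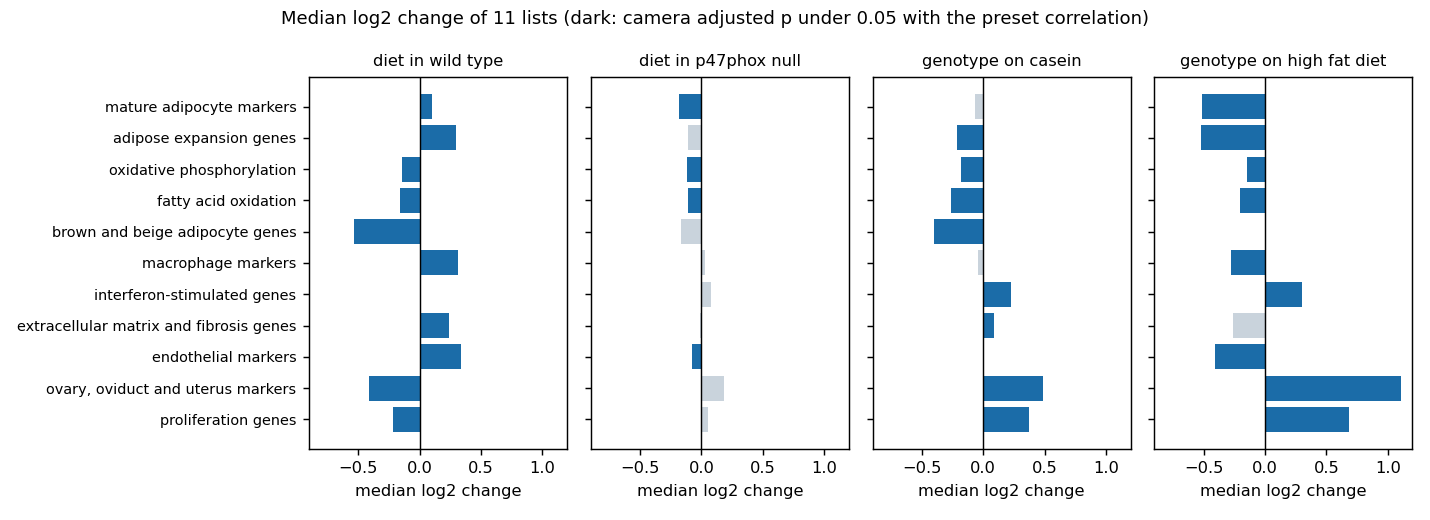
Median log2 change (horizontal axis) of 11 gene lists (vertical axis) in the 4 comparisons; dark bars passed camera with the preset correlation, and none did with an estimated correlation. The ovary, oviduct and uterus markers are at 1.11 and the adipose expansion genes at -0.52 between the genotypes on the high fat diet.

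The interaction asks whether the diet change differs between the genotypes. Tst, a mitochondrial sulfurtransferase, had a difference of 1.78 ± 0.32 (SE, n = 3 pools a group), Dusp14, a phosphatase, of 1.24 ± 0.24, Sycp3, a synaptonemal complex protein, of -0.87 ± 0.16 and Il4i1, an amino acid oxidase, of -0.49 ± 0.09, all at adjusted p = 0.789, the smallest of this comparison. The differences were -1.58 ± 0.66 for Mest (adjusted p = 0.789), -0.76 ± 0.40 for Lep (adjusted p = 0.791), -1.20 ± 0.51 for Npr3 (adjusted p = 0.789), -0.82 ± 0.43 for Ccl2 (adjusted p = 0.791), -0.63 ± 0.25 for Adgre1 (adjusted p = 0.789) and -0.12 ± 0.23 for Ncf1 (adjusted p = 0.928). Without wild type high fat diet pool 3 the difference was -1.03 for Mest, -0.39 for Lep and -0.42 for Ccl2, and that of Npr3 was -0.74 without null casein pool 1. Thus 0 of 18195 genes passed in limma, with 1113 at an unadjusted p under 0.05. The count was 10 without wild type casein pool 2 and 1 without wild type casein pool 3. Camera called 12 lists, 7 without wild type high fat diet pool 3 or null high fat diet pool 3, and fry 0. Lower in null pools, as a difference of diet changes, were endothelial markers at -0.44, mature adipocyte markers at -0.43 and adipose expansion genes at -0.38 (each adjusted p = 0.631 with an estimated correlation) and macrophage markers at -0.27 (adjusted p = 0.733 with an estimated correlation), and higher were ovary, oviduct and uterus markers at 0.80 (adjusted p = 0.631 with an estimated correlation). No member passed over all genes or adjusted over the list alone in these 5 lists. Of these 5, the macrophage call ended without wild type high fat diet pool 3 (median -0.11), and its median was -0.405 without wild type high fat diet pool 1. The mature adipocyte median was -0.29 without null high fat diet pool 3, and the median of the ovary, oviduct and uterus markers was 0.48 without wild type casein pool 1.

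Across the 18195 genes, which are not independent replicates, the diet changes of the genotypes had a Pearson correlation of -0.109 (Spearman -0.074), and of the 1384 genes at an unadjusted p under 0.05 in wild type 49.6% went the same way in null pools. The genotype differences on the 2 diets had a Pearson correlation of 0.607 (Spearman 0.511), and 89.7% of the 1478 genes at an unadjusted p under 0.05 on casein went the same way on the high fat diet, against 68.0% of all genes. The means of Mest, Lep and Npr3 were lower and that of Ide was higher in null pools on each diet. The first correlation ran from -0.231 without null casein pool 3 to 0.125 without null casein pool 1, was 0.104 without wild type casein pool 1 and 0.038 without null high fat diet pool 3. The second was 0.289 without wild type casein pool 2 and 0.466 without null casein pool 3.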

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

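The tests of explanations in this part were all chosen after the result was seen, while the camera test of the interaction for each list was part of the plan. Diet changes differed between the genotypes for 12 lists by that test with its preset correlation, and for 0 with an estimated correlation (adjusted p from 0.631 to 0.733 with an estimated correlation). As the median of the diet change in null minus that in wild type pools, the differences were -0.44 for endothelial markers, -0.43 for mature adipocyte markers, -0.38 for adipose expansion genes, -0.27 for macrophage markers, -0.26 for erythroid genes, -0.22 for extracellular matrix and fibrosis genes, -0.22 for adipocyte progenitor and fibroblast markers and -0.16 for inflammatory genes. They were 0.80 for ovary, oviduct and uterus markers, 0.53 for brown and beige adipocyte genes, 0.36 for mesothelial markers and 0.29 for proliferation genes. The proliferation genes stood at -0.10 with the tissue medians as covariates. Leaving out 1 pool ended 7 of these list calls. Without wild type high fat diet pool 3 the median was 0.02 for mesothelial markers, -0.11 for macrophage markers, -0.11 for inflammatory genes, -0.16 for matrix genes and 0.47 for brown and beige adipocyte genes. The mesothelial call also ended without wild type casein pool 1 (0.29), null casein pool 3 (0.33) or null high fat diet pool 1 or 3 (0.30 and 0.33), and the proliferation call without wild type casein pool 1 (0.10) or null high fat diet pool 2 or 3 (0.19 and 0.14). The brown and beige call ended without wild type casein pool 2 or 3 (0.32 and 0.58), null casein pool 1 (0.17), wild type high fat diet pool 1 (0.34) or null high fat diet pool 1 or 3 (0.56 and 0.44). The inflammatory call ended without wild type casein pool 1 or 2 (-0.12 and -0.20), null casein pool 3 (-0.13) or null high fat diet pool 1 or 3 (-0.11 and -0.12). The matrix call ended without wild type casein pool 3 (-0.15), and the progenitor and fibroblast call without wild type high fat diet pool 2 (-0.15) or null high fat diet pool 3 (-0.19). Medians of lists still called also moved, without wild type high fat diet pool 1 to 0.71 for mesothelial markers and -0.405 for macrophage markers, and without null high fat diet pool 1 to 0.54 for proliferation genes. They moved to -0.29 for mature adipocyte markers without null high fat diet pool 3, and to 0.48 for ovary, oviduct and uterus markers without wild type casein pool 1.

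A set of 5 genes named in the report had all 3 pools of one diet above the other in 1 genotype and below it in the other, and limma's interaction did not pass for any of them (adjusted p = 0.789). The difference was 1.78 for Tst, which was -1.47 ± 0.24 (SD, n = 3) in wild type and 0.44 ± 0.23 in null pools on the high fat diet, 1.24 for Dusp14, -0.87 for Sycp3, -0.67 for Rgcc, an endothelial list member, and -0.49 for Il4i1. The difference of Rgcc was -0.44 without null casein pool 1. Tst, Dusp14, Sycp3 and Il4i1 were named for the smallest p of the interaction, so their opposite changes were partly built in. The share of all genes with this pattern is not given here, so it is not set apart from chance.

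Ovary, oviduct and uterus markers were higher in null pools on the high fat diet, by 1.02 between the means of the pool medians. Ovary or oviduct tissue collected with some fat pads may account for it: among the 3 wild type casein pools, which share genotype and diet, the list median ranged over 0.77, which is 0.76 of that difference, and Inha was 0.73 in pool 1 against -5.68 and -5.04 in pools 2 and 3. That the p47phox genotype sets the level of oviduct and uterine epithelium genes in every pool is argued against by 2 of the 12 pools. Wild type casein pool 1 and null casein pool 1 were nearer to the other genotype in their median, at 2.5 and -0.51, and Ovgp1 was 3.90 and -3.09 there. Ncf1 was at -0.19 in that null pool, within the null range of -0.29 to -0.19. In that wild type pool Ncf1 was at 0.07, above every null pool but below the other 5 wild type pools (0.37 to 0.85). Ncf1 thus places that pool less clearly. For ovary cell genes the same explanation stays open: 1 pool, wild type casein pool 1 at 0.16, was nearer to the other genotype, against -1.11 to -0.89 in the other 5 wild type pools and 0.04 to 0.83 in the null pools, where null casein pool 1 was at 0.04. A part of the genotype in the amount of such tissue stays open and was not tested.

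As lists, mature adipocyte and adipose expansion genes were called lower in null pools on the high fat diet by camera with its preset correlation, but not with an estimated one (adjusted p = 0.487 and 0.402 with an estimated correlation), and 5 of 23 and 5 of 17 members fell over all genes. Other tissue that dilutes the RNA of the whole fat pad may have a part in this and stays open for the lists: camera called 5 of 7 fat pad lists lower with its preset correlation and 0 with an estimated one, while lipogenesis was at a median of -0.03 and brown and beige adipocyte genes at 0. Dilution would lower adipocyte markers about alike. Lep and Mest differed by -1.18 and -2.3 from the median of the 22 mature adipocyte markers other than Lep (-0.46, SD 0.39), 2.43 and 3.77 times the combined spread. They differed by 1.65 and 3.42 of their own SE from the largest other fall, Aqp7 (-1.17), with Adipoq at -0.20. Lep has the largest fall of the 23 markers, so its excess was partly built in, and Mest is not among them. Mest was also among the genes followed by the plan, and its values argue against dilution as the whole cause of its fall. A part of dilution in the fall of Mest stays open. For Lep, dilution as the whole cause stays open. With the tissue medians as covariates Mest stood at -1.88 ± 0.78 (SE), against -2.76 ± 0.46, and Lep at -0.87 ± 0.48, against -1.64 ± 0.28; both calls ended as the estimates shrank and the errors grew with 5 residual degrees of freedom. An effect of the genotype on fat mass, in the animals the design compares, stays open and was not tested.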

How the results depend on the processing

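The cause of the differences between alternatives was not tested. Of the values of named genes under alternatives, 7203 kept their side of the threshold, 85 newly passed, 343 no longer passed and 6 turned. A turn was counted only where the value passed in either fit, so the 7203 hold values not past the threshold whose sign changed. Of list medians 1216 stayed, 156 no longer passed and 20 turned. Leaving out 1 pool at a time, genes changed ran from 0 to 15 for the diet in wild type, 0 to 1 for the diet in null pools, 0 to 46 for the genotype on casein, 0 to 1617 for the genotype on the high fat diet, 0 to 10 for the interaction, 157 to 2339 for the genotype averaged and 0 to 9 for the diet averaged. Lists called ran from 10 to 16, 2 to 10, 5 to 12, 10 to 14 and 7 to 13 for the 5 comparisons in that order. The correlation of diet changes ran from -0.231 to 0.125, and that of genotype differences from 0.289 to 0.695. Ncf1 on the high fat diet ran from -0.844 to -0.668, with estimates of -0.844, -0.781 and -0.668 without wild type high fat diet pools 1, 2 and 3, -0.773 and -0.784 without null high fat diet pools 2 and 3, and -0.764 without null casein pool 2, where the call ended as the error grew to 0.172 from 0.163.

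Counts of genes changed under other settings were, for the diet in wild type, 1 without the 3 pools that stand apart and 238 at an unadjusted p under 0.05 with at least a 1.5-fold change. For the diet in null pools they were 1 with trend and robust settings, 942 with array weights and 67 at the unadjusted threshold. For the genotype on casein they were 1 after quantile normalization again and 208 at the unadjusted threshold, and for the interaction 339 at that threshold. For the genotype on the high fat diet they were 5116 with array weights, 655 after quantile normalization, 0 with the tissue list medians as covariates and 440 without the 3 pools. They were 732 there with the probe set of the highest mean, the rule of the plan. For the genotype averaged they were 4009 with array weights, 0 with covariates, 548 without the 3 pools and 641 at the unadjusted threshold. For the diet averaged they were 3 with trend and robust settings, 5 with array weights, 0 after quantile normalization, 2 with covariates and 48 at the unadjusted threshold. Lists called were 0 in all 5 comparisons with an estimated correlation, and 0 with fry except 7 for the genotype on the high fat diet. They were 4 for the diet in null pools with a stricter filter, with quantile normalization and with the genes of larger SD, 7 for the genotype on casein with a stricter filter and without the 3 pools, and 3 for the genotype on the high fat diet with covariates. The correlation of diet changes was 0.02 after quantile normalization and 0.323 with covariates. Ncf1 on the high fat diet was -0.764 ± 0.237 (adjusted p = 0.0628) with trend and robust settings, where the error grew from 0.163. With covariates Ncf1 was -0.607 ± 0.202 (adjusted p = 0.709), where the estimate shrank and the error grew.

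Pool numbers as a replicate block gave 542 genes for the genotype on the high fat diet, 829 for the genotype averaged and 0 for the diet averaged, where the call of Hsd11b1 ended. In the check of that pairing, pools of the same number had correlations from -0.615 to 0.59, so the numbers were not taken as pairs.

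The reproductive tract covariate separated the genotypes on the high fat diet, so it takes up part of that genotype difference itself. Directions turned with the tissue list medians as covariates for several lists. For the diet in null pools these were mature adipocyte markers at 0.021, fatty acid oxidation at 0.047 and endothelial markers at 0.059. For the genotype on casein they were fatty acid oxidation at 0.057, mammary and other epithelial markers at -0.014 and ovary, oviduct and uterus markers at -0.031, a list that is itself a covariate. For the genotype on the high fat diet they were mature adipocyte markers at 0.088, fatty acid oxidation at 0.406, oxidative phosphorylation at 0.162, progenitor and fibroblast markers at 0.063, endothelial markers at 0.043, mammary and other epithelial markers at -0.247 and proliferation genes at -0.081, and for the interaction proliferation genes at -0.099. Of these, camera called 4 in the opposite direction, fatty acid oxidation and mammary and other epithelial markers for the genotype on the high fat diet, the mammary list for the genotype on casein, and proliferation genes for the interaction. The others were not called. Of the 38 named genes that passed on the high fat diet, 6 turned, Cebpa to 0.025, Wfdc18 to -0.255, Clu to -0.273, Ccnb2 to -0.384, Cdk1 to -0.015 and Rrm2 to -0.092, and the other 32 no longer passed. Lymphocyte markers turned to 0.17 for the diet in wild type without the 3 pools, and leaving out 1 pool ran from -0.566 without wild type casein pool 1 to 0.096 without wild type casein pool 3. For the genotype on casein they turned to 0.024 without the 3 pools, and leaving out 1 pool ran from -0.735 without wild type casein pool 1 to 0.024 without wild type casein pool 3. Extracellular matrix and fibrosis genes turned to -0.003 for the genotype on casein without the 3 pools, and leaving out 1 pool ran from -0.003 without wild type casein pool 3 to 0.138 without wild type casein pool 2.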

Other observations

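The comparisons averaged over diet or genotype, the tissue lists, the tests of the explanations of Ide and Fgfbp3 and the splits of the samples were chosen after the results were seen. Averaged over the genotypes, Hsd11b1, the enzyme that regenerates active glucocorticoid in fat, fell by 1.89 ± 0.19 on the high fat diet (SE; limma adjusted p = 0.0164), and was lower in all 6 high fat diet pools, at -1.40 to -0.49, than in all 6 casein pools, at 0.49 to 1.48. It was the only 1 of 18195 genes to pass, with 952 at an unadjusted p under 0.05. The count was 0 without null casein pool 2 or 3, wild type high fat diet pool 3, or null high fat diet pool 1, 2 or 3. It was 2 without wild type casein pool 1 or 3 or wild type high fat diet pool 2, 6 without wild type high fat diet pool 1 and 9 without wild type casein pool 2. It was 0 after quantile normalization again, and without the 3 pools that stand apart the 1 gene that passed was another, higher gene, so the call of Hsd11b1 ended there too. Averaged over the diets, 1368 genes differed between the genotypes, 745 higher and 623 lower in null pools. Nol3 fell by 1.07 ± 0.10 (adjusted p = 0.00331), Snx7, a sorting nexin, fell by 0.77 ± 0.07, Adamts5, an aggrecan-cleaving protease, fell by 0.84 ± 0.08, and Hirip3 rose by 0.51 ± 0.05; Snx7 and Adamts5 were chosen after their values were seen. Of 28 proliferation genes 14 rose over all genes and 24 adjusted over the list alone (adjusted p = 0.47 with an estimated correlation), and of 29 interferon-stimulated genes 7 rose and 11 adjusted over the list alone (adjusted p = 0.346 with an estimated correlation). In the same comparison 7 of 23 ovary, oviduct and uterus markers rose and 16 adjusted over the list alone, with a median of 0.95 (adjusted p = 0.346 with an estimated correlation). With the tissue medians as covariates 0 genes passed, and the proliferation median was -0.03 and the interferon-stimulated median 0.14. The count of 1368 was 2339 without wild type casein pool 1, 360 and 716 without wild type casein pools 2 and 3, 157 and 323 without null casein pools 2 and 3, 561, 669 and 455 without wild type high fat diet pools 1, 2 and 3, and 252 and 357 without null high fat diet pools 2 and 3.

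Markers of other tissues were high in some pools, and the genes are named here after their values were seen. In wild type casein pool 3, Cyp11b1, the adrenal enzyme of corticosterone synthesis, was at 8.56 and Chgb, of adrenal chromaffin cells, at 8.17, where the other 11 pools were at or below 0.95 and 0.50; Alb and Ttr, secreted by the liver, were at 4.64 and 4.67. Myh4, a myosin of fast muscle fibres, ran from -2.89 in null high fat diet pool 2 to 5.03 in wild type high fat diet pool 2. Ovgp1, of the oviduct epithelium, was at 3.90 in wild type casein pool 1 and at or below -3.80 in the other 5 wild type pools, and in null pools ran from -3.09 to 4.77. The median of 15 ovary cell genes ran from -1.04 to -0.90 in wild type and from 0.08 to 0.83 in null pools on the high fat diet, and that of 10 oviduct and uterine epithelium genes was 2.5 in wild type casein pool 1 and 1.95 in null high fat diet pool 3. The median of 8 kidney genes was 1.51 in null casein pool 3 and at most 0.13 in the others.

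Ide, the insulin-degrading enzyme, and Fgfbp3, a growth factor binding protein, which are near neighbours on a chromosome and of which Fgfbp3 was chosen after its values were seen, were higher in all 6 null pools than in all 6 wild type pools, Ide by 0.61 ± 0.07 averaged over the diets (SE; adjusted p = 0.00548) and Fgfbp3 by 0.87 on casein and 1.14 on the high fat diet (adjusted p = 0.184 and 0.0112). A copy gain of the whole stretch between them in the null stock is argued against, since 0 of the 4 measured genes between them was higher in every null pool; among these Btaf1 differed by -0.05 ± 0.06 and Cpeb3 fell by 0.35 ± 0.08 (adjusted p = 0.0347). A gain of a part of the stretch stays open, since an unnamed clone between them rose by 0.80 ± 0.14 averaged over the diets (adjusted p = 0.0165), with differences of 1.17 on casein and 0.43 on the high fat diet, though its lowest null pool (-0.06) was below the highest wild type pool (0.13). Null and wild type stocks from different C57BL/6 substrains may account for the pair, and this stays open: Nnt, which one substrain lacks in part, differed by 0.12 ± 0.13 over 3 probe sets, and a probe set outside the missing part would not show it. A change in Ide and Fgfbp3 that follows from the loss of p47phox was not tested. In all, 231 genes were higher and 328 lower in every null than in every wild type pool.

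Other splits of the same samples were counted. For the 4 comparisons of 3 pools with 3, the 10 splits are too few for a share under 0.05. The real count of genes was 1077 on the high fat diet between genotypes, with 1 as the highest of the other splits; on casein it was 0, with 85; for the diet it was 0 in wild type, with 0, and 0 in null pools, with 1. The real counts of lists were 13, 12, 14 and 7 in that order, and the highest of the other splits were 15, 14, 15 and 13. The split of the casein pools that called 85 genes points to a structure of the samples other than the groups.

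For the interaction the real count of genes was 0, which every split reaches, so the 100 splits drawn cannot test it. The highest count was 2003. A split that moves pools between the genotypes can carry the genotype difference into the interaction, so the source of that count stays open. As many lists as the real 12 came from 37 of 100 splits, with 18 as the highest. Chance is not excluded for the lists, and the same limit of the splits holds for them. For the genotype averaged over the diets only the real split of 100 gave as many as 1368 genes, with 468 as the highest other, a share under 0.05. The splits cannot tell the genotype from other tissue that falls unevenly between the genotypes. The count was 157 without null casein pool 2 and 0 with the tissue list medians as covariates. For lists 31 of 100 splits gave as many as 12, with 17 as the highest. For the diet averaged over the genotypes 3 of 100 splits gave 1 gene or more, a share under 0.05, but another split gave 3 genes against the real 1, so the count is not taken as set apart from chance. For lists 37 of 100 gave as many as 11, with 16 as the highest.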
